A study of Danio rerio with 9 samples.

How the data were processed

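Gene expression was measured in 9 samples of sorted zebrafish leukaemia cells, 6 from the hMYC-ER model and 3 from the hlk model, with 1 array per sample. Per the labels' protocols, green fluorescent T-lymphoblasts were sorted from fish at the end of the disease, RNA was extracted with Trizol, and biotin-labelled cRNA was made by the Affymetrix procedure from 100 ng of total RNA. The deposited table holds 1 intensity per probe set and array on a linear scale. The authors had already scaled these intensities, because the mean signal after trimming 2% of the probe sets at each end was 500.1 or 500.2 on every array, but the algorithm that made the signals is not given in the sources used here. Detection calls and scanner files were not used here.

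The table holds 15617 probe sets. The 115 control probe sets of the array maker were left out of the tests, so that 15502 were tested. No column lacked a sample and no pair of arrays held identical values. Gene names came from the platform annotation, updated through the Entrez identifier with a gene table of assembly GRCz12tu that was used for names only. Of the tested probe sets, 10795 had 1 gene symbol, 135 had several and 4572 had none. The Entrez identifier found 10718 of the symbols and changed 1. Probe sets without a symbol are unnamed here, and none was named from a probe set with several symbols. For statements on genes, the probe set with the highest mean over all 9 arrays stood for each symbol. This gave 8793 genes, of which 1539 had more than 1 probe set. Of the 333 changed genes with more than 1 probe set, all probe sets of 235 lay in the same direction. No build is named in the files, so no coordinates are given.

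Main settings, tests, gene lists and naming rules were fixed before the data were examined. By that plan a linear table was to be floored at a signal of 16 and put on the log2 scale, with quantile normalization only if the array medians of log2 signal differed by more than 0.1. They differed by 0.31, so the arrays were quantile normalized first and then floored, which places the floor at 4 on the log2 scale. Between 15.8% and 20.2% of the tested signals on each array lay below the floor. A difference against a group that lies wholly at the floor is a lower bound, given as "at least". All differences are hMYC-ER minus hlk on this log2 scale, and they understate the change of genes near the floor.

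The models were compared with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, with Benjamini-Hochberg adjustment over all probe sets or over all genes and an adjusted p threshold of 0.05. Every adjusted p of a gene or probe set comes from limma. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The fit included all 9 arrays and no covariate, since the labels give no batch, date or litter. For 13 biology lists and 13 marker lists of other cell types, limma's camera tested whether the members differed from the other genes, with a preset correlation of 0.01 and adjustment within each kind of list. Lists with fewer than 5 measured members were described only, which left 13 and 12 tested lists. The distance between arrays was 1 minus Pearson's r over genes, and between minus within distances were tested by exact permutation over all 84 splits of 9 arrays into 6 and 3.

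Genes were named by a fixed rule. It took the 12 largest changes per direction among changed genes with a proper symbol whose 3 hlk values lay on 1 side of all 6 hMYC-ER values, up to 4 changed members with the smallest p in each list, and, where no member of a list passed, the 2 with the smallest p. It also named a set of genes of interest, of which lck, ptenb, ccr7, ccr9a, ccr9b, itga4, itgb1a and itgb2 had no named probe set here, and 1 more gene is not reported here. The rule gave 101 genes. No probe set is annotated as the human MYC transgene, so its level was not analysed here.

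The fit was tried on simulated arrays with the mean and the pooled within-model SD of each of the 15502 probe sets and known changes in probe sets with a mean signal above 64. The fit found 56% of the simulated log2 changes of 1, 74% of those of 2, 94% of those of 3 and 100% of those of 4, with 50 probe sets per size. It made 13 false calls, 7.43% of all its calls. Far fewer probe sets changed in the simulation than the 2932 called in the data. The adjustment depends on that number, so these rates need not hold for the real comparison.

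Alternatives fixed in advance were centring each array on its median, leaving out the dimmest 1 in 3 probe sets, floors of 1 and 64, an intensity trend with a robust prior, array weights, leaving out each array in turn, a 2-fold minimum, an unadjusted p under 0.001, an exact rank test, the mean of all probe sets of a gene, an estimated correlation in camera, limma's fry, and Spearman correlation for the distances. The signals as deposited, without quantile normalization, and a closer look at the fit without hlk array 7 were added after seeing the data.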

Results

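Expression profiles were collected from green fluorescent T-lymphoblasts sorted from zebrafish with T cell acute lymphoblastic leukaemia at the final stage of disease. 6 arrays came from the hMYC-ER model, in which human MYC is fused to part of the oestrogen receptor, and 3 came from hlk, a heritable zebrafish line prone to T cell malignancy. The design compares the 2 models as classes, and the series title concerns spread of the leukaemia to the central nervous system. Arrays are named here by the sample numbers in the labels, 1 to 6 for hMYC-ER and 7 to 9 for hlk. The labels do not say that the arrays come from separate fish, so that p-values measure the spread between these samples, which may be technical. Scan dates and batches are not given in the sources used here, and a batch that followed the model cannot be told apart from it.

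The median signal per array ran from 88.9 to 110.3, with the authors' trimmed mean at 500.1 or 500.2 throughout. The gapdhs control, whose probe sets at the 3' and 5' ends of the transcript compare RNA integrity, had a 3' to 5' ratio of 50.8 on hlk array 7 and of 2.20 to 4.50 on the other 8 arrays. On array 7 the 5' signal was 227.8, against 2951 to 6621 elsewhere. This array also had the lowest array weight, 0.30 against 0.73 to 1.80.

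The models differed widely. Of 8793 genes, 1932 (22.0%) were changed, 916 higher in hMYC-ER and 1016 higher in hlk, and 1154 of these differed at least 2-fold, 643 higher in hMYC-ER and 511 higher in hlk. At the level of probe sets, 2932 of 15502 changed, 1410 higher in hMYC-ER and 1522 higher in hlk. The 6 hMYC-ER values and the 3 hlk values did not overlap for 2035 genes (23.1%), where chance gives 2.38%. When hlk array 7 was left out, 1978 genes were changed, and 1536 of the 1932 genes (79.5%) were among them with the same direction and 0 with the opposite direction. The median difference of all genes was -0.08, and -0.18 when each array was centred on its median, so small differences are read against that shift. An exact rank test on 6 against 3 arrays called 0 genes after adjustment, where its smallest adjusted p was 0.102, and 2586 genes at an unadjusted p under 0.05, against 3032 for limma.

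Towards hMYC-ER, the gene for the cytosolic NADPH oxidase subunit ncf1 stood at 13.66 ± 0.32 (SD, n = 6) in hMYC-ER and 5.73 ± 0.30 (SD, n = 3) in hlk, a difference of 7.93 (SE 0.22, adjusted p 5.0e-07). The thymosin gene tmsb, which encodes an actin-binding peptide, was at least 224-fold higher in hMYC-ER, with all 3 hlk arrays at the floor (adjusted p 3.2e-08). The immunoglobulin light chain gene igl1c1 reached 14.04 ± 0.10 (SD, n = 6) against 6.32 ± 0.41 (SD, n = 3), a difference of 7.72 (SE 0.17, adjusted p 1.1e-07). The others of the 12 genes named by size were hopx (7.75), the spectrin gene sptbn1 (7.34, with 3 of 3 probe sets changed), the chemokine receptor gene cxcr4a (7.33), plekhh1 (7.03), the Notch ligand gene dlc (6.94), the junctional adhesion gene jam2a (6.85), the pigment cell regulator mitfa (6.85), and the B lineage genes pax5 (6.78) and blnk (6.55), with adjusted p of 6.7e-05 or less.

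Towards hlk, the 12 genes named by size began with the homeobox gene ved, at 4.45 ± 0.43 (SD, n = 6) in hMYC-ER and 11.82 ± 0.43 (SD, n = 3) in hlk, a difference of -7.37 (SE 0.29, adjusted p 2.2e-06). The secreted Wnt ligand gene wnt11 lay at the floor on 5 of 6 hMYC-ER arrays and at 10.57 ± 0.63 (SD, n = 3) in hlk (-6.55, SE 0.23, adjusted p 1.1e-06), and the N-cadherin gene cdh2 differed by -6.20 (SE 0.33, adjusted p 8.8e-06). The remaining genes were the glycosyltransferase gene b3gnt5a (-7.23), sv2bb (-7.10), cyld2 (-6.77), palm1b (-6.08), the Ras pathway inhibitor spred1 (-6.08), carmil2 (-6.06), the semaphorin gene sema4e (-5.84), the filamin gene flncb (-5.77) and arpp21 (-5.72), with adjusted p of 7.7e-04 or less. Of the probe sets of spred1, 1 of 4 passed, and of those of cdh2, 1 of 2. All 24 genes named by size kept their call and direction in every alternative limma fit that measured them. They were picked for their size on these same arrays, and the exact rank test called none of them.

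Of the 21 listed B cell markers, 8 were measured. All 8 were higher in hMYC-ER, also when adjusted over the list alone. The list median was 4.78. The transcription factor gene pax5, which commits lymphoid cells to the B lineage, stood at 11.09 ± 0.15 (SD, n = 6) against 4.31 ± 0.53 (SD, n = 3), and the B cell receptor adaptor gene blnk at 11.05 ± 0.31 (SD, n = 6) against 4.50 ± 0.80 (SD, n = 3). Differences were also found for the kinase genes btk (5.40) and syk (4.27), the transcription factor gene spi1b (5.29, both of its probe sets changed), the antigen presentation genes cd74b (2.85) and cd74a (2.23), and mhc2dcb (1.39). A further probe set of pax5 near the floor differed by 0.14 (adjusted p 0.809). The list as a whole was shifted towards hMYC-ER (camera adjusted p 1.1e-11), and this call was kept with an estimated correlation (adjusted p 0.0069). With hlk array 7 left out, the median was 4.78 and 7 of the 8 genes were changed.

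Genes of T cell identity moved towards hlk where they moved. Of the 36 listed genes, 13 were measured. Of these, 4 were higher in hlk, 0 were higher in hMYC-ER and 9 did not pass, with the same counts when adjusted over the list alone. The T cell receptor alpha constant gene trac stood at 7.01 ± 0.95 (SD, n = 6) in hMYC-ER and 11.61 ± 1.32 (SD, n = 3) in hlk, a difference of -4.60 (SE 0.70, adjusted p 0.00228). For trac, 3 of 3 probe sets lay in this direction and 1 passed. The T lineage transcription factor gene gata3 differed by -4.70 (SE 0.63, adjusted p 0.00133) and ets1 by -4.28 (SE 0.33, adjusted p 6.4e-05, 1 of 2 probe sets changed). The gene runx3 differed by -3.51 (SE 0.35, adjusted p 2.8e-04, both probe sets changed). The whole list had a median of -0.40 and was not shifted (camera adjusted p 0.116). Without hlk array 7 its median was -0.615 (camera adjusted p 0.151). The B cell markers above rose in the same arrays in which these genes were low.

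In the list for V(D)J recombination and early thymocyte factors, 5 of 16 measured genes were higher in hlk, 1 was higher in hMYC-ER and 10 did not pass, with the same counts when adjusted over the list alone. The Artemis nuclease gene dclre1c differed by -2.88 (adjusted p 0.00102), hmgb1a by -0.64 (adjusted p 0.0237) and the polymerase gene poll by -0.49 (adjusted p 0.0163), and the E protein gene tcf12 was higher in hMYC-ER by 2.17 (adjusted p 0.00642, 4 of 4 probe sets). The recombinase gene rag1 stood at 6.80 ± 1.01 (SD, n = 6) against 10.91 ± 3.22 (SD, n = 3), a difference of -4.12 (adjusted p 0.0475). Its value on hlk array 7 was 7.21, far below the 13.13 and 12.39 of arrays 8 and 9, and without array 7 the difference was -5.96 (adjusted p 0.00138). The partner gene rag2 stood at 8.75 ± 1.50 (SD, n = 6) and 7.50 ± 3.09 (SD, n = 3), and its difference of 1.25 did not pass (adjusted p 0.567) and became -0.50 without array 7 (adjusted p 0.792). The list was not shifted (median -0.28, camera adjusted p 0.265), the call of hmgb1a ended without array 7 (-0.49, adjusted p 0.0654) and without array 8 (-0.67, adjusted p 0.0507), and that of rag1 ended without any 1 of the other 8 arrays (adjusted p up to 0.16, where the difference was -3.37 without array 9).

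**Figure D1:**
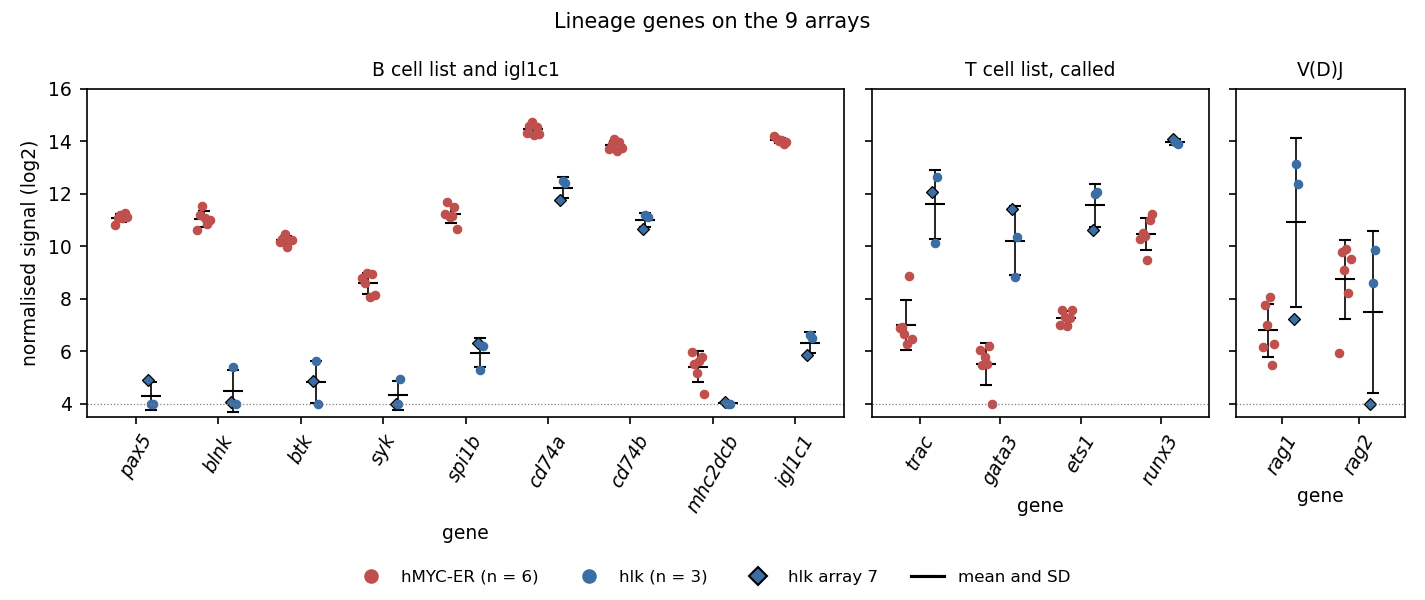
Normalised log2 signal (y axis, floor at 4) of B cell, T cell and V(D)J genes (x axis) on each of 6 hMYC-ER arrays (red) and 3 hlk arrays (blue; hlk array 7 as a diamond), with black marks for the mean and SD. The 6 igl1c1 values in hMYC-ER lie between 13.90 and 14.20 and the 3 hlk values between 5.86 and 6.61, while the 3 trac values in hlk, 10.13 to 12.65, all lie above the hMYC-ER values.

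The zebrafish MYC family genes went different ways. The gene myca stood at 8.80 ± 0.28 (SD, n = 6) in hMYC-ER and 13.10 ± 0.27 (SD, n = 3) in hlk, a difference of -4.29 (SE 0.19, adjusted p 3.9e-06), whereas mych stood at 12.54 ± 0.35 (SD, n = 6) and 9.77 ± 0.37 (SD, n = 3), a difference of 2.77 (SE 0.24, adjusted p 1.3e-04). Neither mycb (-1.16, SE 0.67, adjusted p 0.262) nor mycn (0.09, SE 0.65, adjusted p 0.950) passed, the mycb difference ran from -1.87 without hlk array 9 to -0.17 without hlk array 8, and the sign of mycn turned when arrays were centred on their medians (-0.07). In the list of oncogenes and tumour suppressors of T cell leukaemia, 5 of 33 measured genes were higher in hlk and 2 in hMYC-ER, and 26 did not pass. Adjusted over the list alone, 4 were higher in hlk and 2 in hMYC-ER. Besides the MYC genes, the histone methyltransferase gene ezh2 (-1.76, adjusted p 0.00141) and the survival gene bcl2l1 (-0.99, adjusted p 0.0106; a dimmer probe set gave 0.28, adjusted p 0.612) were higher in hlk. Values for ptena (-0.11, SE 0.22, adjusted p 0.760), notch1a (-0.26, SE 0.50, adjusted p 0.767) and notch1b (0.65, SE 0.56, adjusted p 0.465) did not pass, and the list was not shifted (median -0.11, camera adjusted p 0.420). The fit without hlk array 7 gave -0.43 for ptena (adjusted p 0.0391).

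Of 51 measured ribosome biogenesis genes, a group that MYC is known to activate, 24 were higher in hMYC-ER, 1 was higher in hlk and 26 did not pass. Adjusted over the list alone the counts were 29 and 1. The list median was 0.51. The Myb-binding nucleolar gene mybbp1a stood at 11.97 ± 0.17 (SD, n = 6) against 10.47 ± 0.16 (SD, n = 3), a difference of 1.50 (SE 0.13, adjusted p 1.2e-04, 4 of 4 probe sets), and rcl1 (1.50, adjusted p 1.4e-04) and pa2g4a (0.74, adjusted p 7.6e-04) were also higher. The processing factor gene bop1 went the other way (-1.33, adjusted p 0.00168). The shift passed with the preset correlation (camera adjusted p 1.2e-09) and did not pass with an estimated correlation (adjusted p = 0.140). Leaving out hlk array 7 gave 25 members higher in hMYC-ER and 1 in hlk.

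Among 31 measured genes of MYC-associated metabolism, 12 were higher in hMYC-ER and 3 in hlk, with the same counts when adjusted over the list alone, and 16 did not pass. The CTP synthase gene ctps1a stood at 14.04 ± 0.15 (SD, n = 6) against 11.58 ± 0.25 (SD, n = 3), a difference of 2.47 (SE 0.14, adjusted p 1.3e-05). The purine synthesis gene ppat (1.75, adjusted p 4.3e-04) and the translation regulator eif4ebp1 (1.75, adjusted p 4.7e-04) were also higher in hMYC-ER, and the mitochondrial serine hydroxymethyltransferase gene shmt2 was higher in hlk (-2.38, adjusted p 1.1e-04; a probe set near the floor gave 0.02). The median was 0.38 and the shift passed with the preset correlation (camera adjusted p 0.00429) but not with an estimated correlation (adjusted p = 0.175). Without hlk array 7 the median was 0.19, with 11 members higher in hMYC-ER and 1 in hlk. Cytosolic ribosomal protein genes, 70 measured, had a median of 0.02, which turned negative relative to other genes when arrays were centred on their medians (camera adjusted p 0.168 and 0.267). Of these, rps26l (0.35, adjusted p 0.0274) and rpl5a (0.26, adjusted p 0.0458) passed, 0 passed when adjusted over the list alone, and the 2 calls ended without any 1 of 5 and of 8 arrays.

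Of 38 measured genes of the heat shock and unfolded protein response, 13 were higher in hMYC-ER, 3 were higher in hlk and 22 did not pass (15 and 3 adjusted over the list alone). The chaperone gene dnajb11 stood at 11.70 ± 0.40 (SD, n = 6) against 8.24 ± 0.35 (SD, n = 3), a difference of 3.46 (SE 0.26, adjusted p 6.0e-05). The unfolded protein response factor gene xbp1, also a regulator of antibody-secreting cells, differed by 3.14 (SE 0.31, adjusted p 2.9e-04), the heat shock factor gene hsf1 by 3.44 (adjusted p 3.5e-04), and the stress gene ddit4, an inhibitor of TOR signalling, by 5.31 (SE 0.73, adjusted p 0.00143). The median was 0.48 and the shift passed with the preset correlation (camera adjusted p 2.6e-04) but not with an estimated correlation (adjusted p = 0.140). In the fit without hlk array 7, 12 members were higher in hMYC-ER and 2 in hlk.

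The apoptosis and growth arrest list was not shifted (median 0.41, camera adjusted p 0.139). Of its 26 measured genes, 3 were higher in hMYC-ER, namely the pro-apoptotic gene bik (2.86, adjusted p 0.00203), the stress gene gadd45aa (2.15, adjusted p 0.00655) and the cyclin gene ccng1 (2.09, adjusted p 0.00676), and 2 were higher in hlk, among them the apoptosis inhibitor gene birc2 (-0.61, adjusted p 0.00381). The counts were the same when adjusted over the list alone, and were 4 and 1 in the fit without hlk array 7. For cell cycle and DNA replication, 2 of 63 genes passed, both higher in hlk, the cyclin genes ccnd1 (-1.64, adjusted p 0.0381) and ccnb3 (-1.44, adjusted p 0.0246), and 0 passed when adjusted over the list alone. This list was not shifted (median -0.37, camera adjusted p 0.139), but the result rested on single arrays. Its adjusted p was 0.0105 without hMYC-ER array 3, 0.00199 without hlk array 8 and 0.935, towards hMYC-ER, without hlk array 9. The call of ccnb3 ended without hlk array 7 (-1.11, adjusted p 0.0831) or 9 (-1.39, adjusted p 0.0750), and that of ccnd1 without any 1 of 8 arrays (-1.84, adjusted p 0.0561, without array 7, and -0.97, adjusted p 0.0521, without array 8).

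Glycolysis genes did not shift as a group (28 measured, 3 higher in hMYC-ER, 2 in hlk, the same adjusted over the list alone, median 0.07, camera adjusted p 0.242). Single members differed by more, with the lactate dehydrogenase gene ldha at 2.50 (adjusted p 6.5e-04), the enolase gene eno1b at 2.85 (adjusted p 0.00326) and the glucose transporter gene slc2a3a at 2.56 (adjusted p 0.00629) towards hMYC-ER. The aldolase gene aldocb was higher in hlk (-1.04, adjusted p 0.0245), a call that ended without any 1 of 4 arrays. A further aldocb probe set gave -0.02. In oxidative phosphorylation, 6 of 80 genes were higher in hMYC-ER and 8 in hlk (6 and 7 adjusted over the list alone, median -0.08, camera adjusted p 0.730). With hlk array 7 left out, 13 were higher in hMYC-ER and 6 in hlk, and the camera direction turned to hMYC-ER (adjusted p 0.702). The same fit gave 3 glycolysis genes higher in hMYC-ER and 4 in hlk, with a list median of 0.157. The cytochrome oxidase subunit genes cox6b1 (-3.29, adjusted p 4.5e-05) and cox5aa (-0.73, adjusted p 0.00248) were higher in hlk. The ATP synthase inhibitor gene atp5if1a (1.11, adjusted p 0.00116) and the ATP synthase subunit gene atp5pf (0.91, adjusted p 0.00206) were higher in hMYC-ER.

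Chemokine receptor, adhesion and migration genes included some of the largest differences. The receptor gene cxcr4a stood at 14.51 ± 0.10 (SD, n = 6) in hMYC-ER and 7.18 ± 0.73 (SD, n = 3) in hlk, and its paralogue cxcr4b at 14.33 ± 0.10 (SD, n = 6) and 10.96 ± 0.21 (SD, n = 3), a difference of 3.37 (SE 0.11, adjusted p 1.0e-06). The junctional adhesion genes jam2a (6.85, adjusted p 3.7e-06) and jam3b were also higher, jam3b at least 26.7-fold with all 3 hlk arrays at the floor (adjusted p 4.6e-05). In all, 9 of 35 measured genes were higher in hMYC-ER and 3 in hlk, and 23 did not pass (9 and 8 adjusted over the list alone). The list was not shifted (camera adjusted p 0.145), its median was -0.10, and its mean of 0.69 and the test pointed to hMYC-ER. Without hlk array 7, 10 were higher in hMYC-ER and 4 in hlk.

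Interferon and inflammatory genes split. Of 24 measured, 4 were higher in hMYC-ER, 7 were higher in hlk and 13 did not pass (5 and 9 adjusted over the list alone). The antigen presentation genes cd74b and cd74a, which are also on the B cell list, and the kinase gene jak2a (1.63, adjusted p 7.6e-05) were higher in hMYC-ER, while the immunoproteasome gene psmb9a was higher in hlk (-2.36, adjusted p 3.9e-04). The list as a whole was not shifted (median -0.39, camera adjusted p 0.726).

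**Figure D2:**
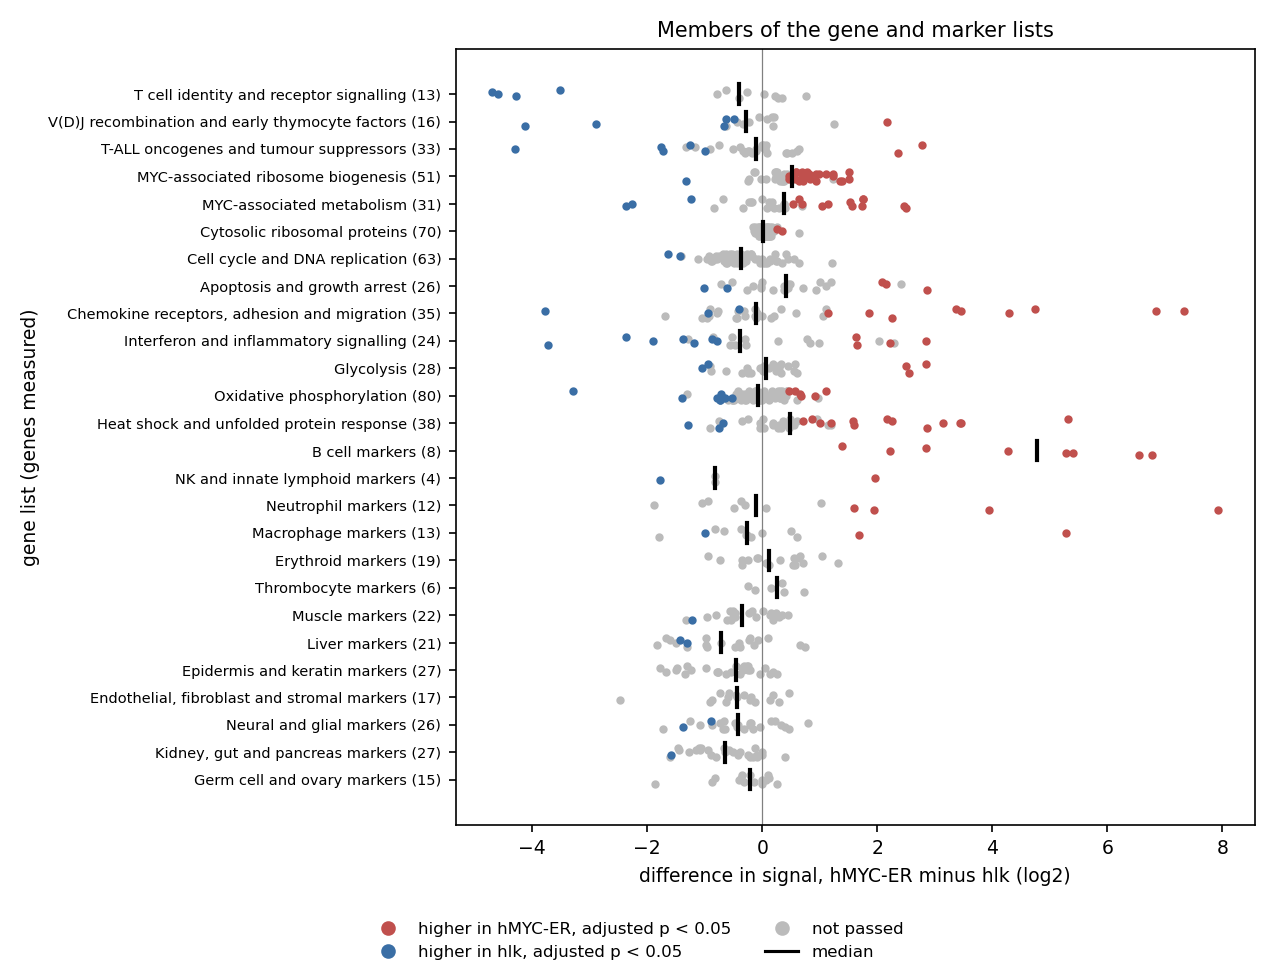
Log2 difference in signal, hMYC-ER minus hlk (x axis), of each measured member of 26 gene lists (y axis, number measured in brackets), with members that passed in red or blue, the rest in grey and the list median as a black bar. The 8 B cell markers all lie to the right, with a median of 4.78, and the 24 red points of ribosome biogenesis lie between 0.46 and 1.50.

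Markers of other cell types showed few changes outside the B cell list. Of 12 neutrophil markers, 4 were higher in hMYC-ER (the same adjusted over the list alone) and 8 did not pass. They were the oxidase genes ncf1, cyba (3.94, adjusted p 1.7e-05; a further probe set gave 0.27, adjusted p 0.511) and ncf4 (1.59, adjusted p 0.00519), and the leukotriene pathway gene alox5ap. For alox5ap all 3 hlk arrays lay at the floor, the difference was at least 3.86-fold (adjusted p 0.0478), and the call ended without any 1 of 8 arrays. The neutrophil list was not shifted (median -0.12, mean 0.96, camera adjusted p 0.146). Without hlk array 7 its median was 0.311, with 3 genes higher in hMYC-ER and 1 in hlk (camera adjusted p 0.285). Of 13 macrophage markers, spi1b, which is also on the B cell list, and grna (1.68, adjusted p 0.00557) were higher in hMYC-ER, and cd68 was higher in hlk (-0.99, adjusted p 0.00103). That list's median was -0.27, its mean 0.20 and its camera adjusted p 0.902. Leaving out hlk array 7 gave it a median of -0.15 (camera adjusted p 0.849). With 4 genes measured, the natural killer list was too small to test, with id2b (1.96, adjusted p 0.0404) higher in hMYC-ER and id2a (-1.78, adjusted p 0.00332) higher in hlk (1 and 2 genes adjusted over the list alone). The id2b call ended without any 1 of 7 arrays (adjusted p up to 0.138, where the difference was 1.52 without hlk array 8).

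For blood and solid tissues, 0 of 19 erythroid, 0 of 6 thrombocyte, 0 of 27 epidermal, 0 of 17 stromal and 0 of 15 germ cell markers passed, by limma over all genes and when adjusted over the list alone. The markers with the smallest p were fech (1.04, adjusted p 0.120) and hbbe2 (-0.94, adjusted p 0.171), thbs1b (0.37 against hlk at the floor, adjusted p 0.197) and f13a1a.1 (0.73, adjusted p 0.257), krt4 (-1.49, adjusted p 0.0782) and krt91 (-1.67, adjusted p 0.0787), tek (-0.91 with hMYC-ER at the floor, adjusted p 0.0573) and fli1 (-2.48, adjusted p 0.115), and zp3b (-0.83, adjusted p 0.0578) and tdrd7a (-1.87, adjusted p 0.151). Small numbers of muscle (1 of 22, mylz3, -1.22), liver (2 of 21, apobb.1, -1.43, and fgb, -1.31), neural (2 of 26, snap25a, -1.38, and fabp7a, -0.90) and kidney, gut and pancreas markers (1 of 27, fabp1b.1, at least 3.02-fold with all 6 hMYC-ER arrays at the floor, a log2 difference of -1.59 that was -0.94 without hlk array 7) were higher in hlk, with 1, 1, 1 and 0 left when adjusted over the list alone. Camera found 0 of the 11 tested marker lists other than B cells to be shifted, with adjusted p of 0.104 or more. Without hlk array 7, fli1 was higher in hlk (-3.98, adjusted p 0.00226), while krt91 (-0.92) and tdrd7a (-0.91) differed by less. The calls of fgb, fabp7a and fabp1b.1 ended without any 1 of 7, 7 and 8 arrays.

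**Figure D3:**
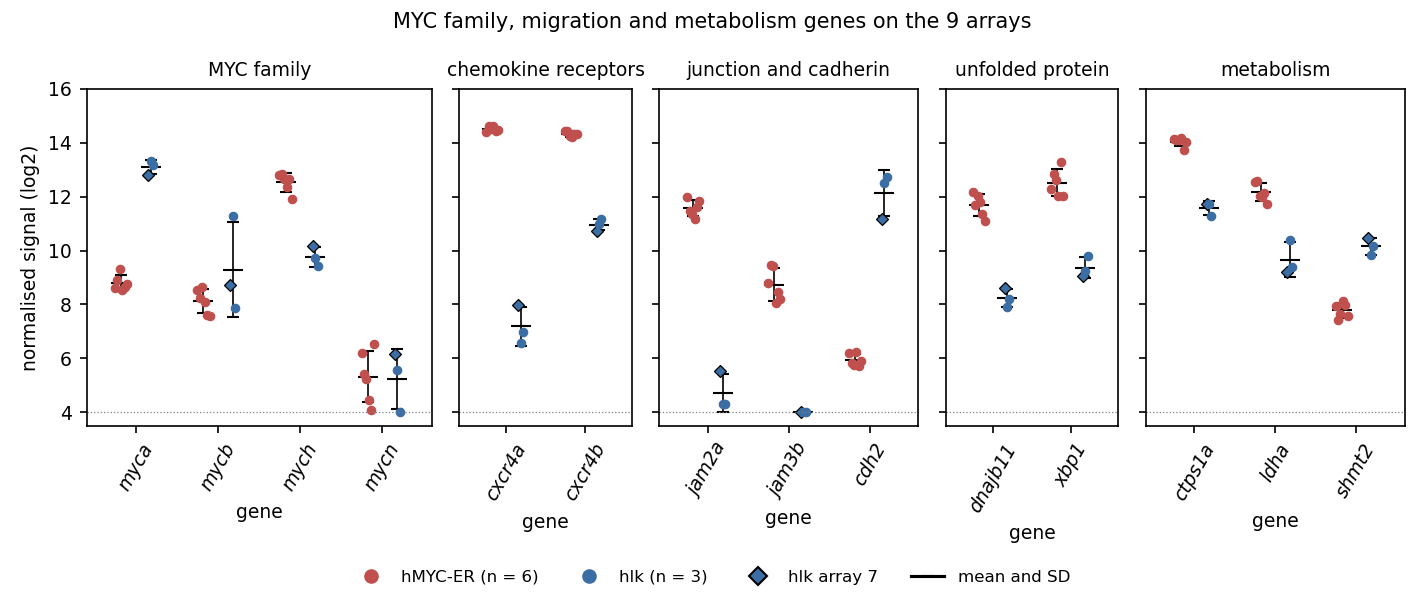
Normalised log2 signal (y axis, floor at 4) of MYC family, chemokine receptor, adhesion, unfolded protein response and metabolism genes (x axis) on each of 6 hMYC-ER arrays (red) and 3 hlk arrays (blue; hlk array 7 as a diamond), with black marks for the mean and SD. The 3 myca values in hlk lie between 12.80 and 13.32, above all 6 hMYC-ER values, and the 6 mych values in hMYC-ER, 11.91 to 12.83, lie above those of hlk.

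Arrays of 1 model were closer to each other than to those of the other model. The mean distance (1 minus Pearson's r over genes) was 0.0297 within hMYC-ER, 0.0685 within hlk and 0.114 between the models. The between minus within distance of 0.0779 was the largest of the 84 splits in a one-sided exact permutation test (p = 0.0119, the smallest that 84 splits can give). The median SD over genes was 0.33 for the 6 hMYC-ER arrays and 0.43 for the 3 hlk arrays, and it was 0.27 for hlk arrays 8 and 9 without array 7. The median correlation within hlk was 0.907 and within hMYC-ER 0.965.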

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

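Of the tests below, those on dilution, on a varying share of B cells, on the 3 scalings, on lineage against the transgene, on neutrophils and on single lists over the 84 splits were chosen only after the result was seen. The second lineage lists were drawn up after the B cell result and before their members' values were seen. A single array far from the other 5 of hMYC-ER was looked for in 132 items, and 21 were found, where chance gives about 1 in 20. The 3 hlk arrays are too few for this rule and were not tested.

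On array 1, hopx lay at 10.58 (12.66 to 13.03 on the other 5), sptbn1 at 12.43 (13.02 to 13.30), the ribosome biogenesis gene rcl1 at 9.85 (10.14 to 10.22) and the egg coat gene zp3b at 4.88 (5.60 to 5.87). The gapdhs 3' to 5' ratio of this array was 4.50, against 2.24 to 2.77. Array 5 stood apart for trac at 8.88 (6.26 to 6.94), carmil2 at 6.75 and wnt11 at 4.11 (both at the floor elsewhere), ctps1a at 13.74 (14.03 to 14.16), the haem synthesis gene fech at 4.00 (5.29 to 5.83), the fibrinogen gene fgb at 5.00 (4.00 to 4.14) and the mean of the apoptosis and growth arrest list at 8.64 (8.89 to 9.01). Array 6 lay lower for gata3, at 4.00 (5.48 to 6.22), and for cox6b1, at 9.37 (10.10 to 10.26). Its BioB and CreX hybridization controls gave 1113 (557 to 733) and 45020 (20920 to 28160). Array 3 was low for notch1a at 4.94 (6.20 to 6.63), notch1b at 4.21 (5.29 to 5.88) and the erythroid list mean at 5.22 (5.57 to 5.77). Array 4 was high for snap25a at 4.22 (floor elsewhere) and for the mean of the kidney, gut and pancreas list at 5.09 (4.61 to 4.79).

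The array maker's further control probe sets, those for gapdhs and acta1 left out, include reporter sequences such as EGFP and DsRed. No comparison above used them. Of these, 4 differed between the models by at least 3 on the log2 scale. AFFX-Dr-M62653-1_s_at was higher in hMYC-ER by 8.95 (signals 7968 to 12090 against 2.91 to 33.9), AFFX-Dr-AF292560-1_s_at by at least 8.70 and AFFX-Dr-AF292559-1_at by at least 6.14, the last 2 with all hlk arrays at the floor. AFFX-Dr-U43284-1_s_at was lower in hMYC-ER (-3.20, signals 760 to 1893 against 6725 to 16186). The sequences behind these identifiers were not analysed here. The cells were sorted by green fluorescence, but the EGFP probe set AFFX-Dr-pd2EGFP_at was dim in both models. It stood at 5.82 ± 1.16 (SD, n = 6) in hMYC-ER and 5.08 ± 1.05 (SD, n = 3) in hlk (adjusted p 0.559). Which fluorescent protein the cells carried was not tested.

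The B cell markers were high and several T cell genes low on arrays labelled as hMYC-ER T-lymphoblasts. Poor RNA on hlk array 7 is excluded as the cause, since the list median without it was 4.78. Dilution of T-lymphoblasts by less than an equal number of other cells would lower a gene by at most 1. That bound takes equal RNA per cell and like T-lymphoblasts in both models, neither of which was measured. The 4 T cell genes that passed differed by more, with trac at -4.60 (SE 0.70), gata3 at -4.70 (SE 0.63), ets1 at -4.28 (SE 0.33) and runx3 at -3.51 (SE 0.35). These values argue against such dilution as the only cause for these 4 genes. For the list as a whole it remains open. The median of the 13 measured T cell genes was -0.404 and they ranged from -4.70 to 0.755. The other genes of the 36 listed were not measured, so the median says little about the whole list. A larger share of other cells could lower genes further and was not tested. Admixed B cells may still have contributed. A varying share remains open, with the spread of the B cell list at percentile 65.7 of 10000 random lists, and a constant share was not tested. That the sorted cells might be of B lineage remains open as well. A second B lineage list rose (5 of 7 genes, median 1.93, camera p 0.00155). A second T lineage list did not fall (1 of 5 genes rose, median 0.43, camera p 0.288). With 5 measured genes that T list cannot decide the question, and its result is not evidence against B lineage. The high B cell markers and low T cell genes go with B lineage, but they are the values that raised the question.

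The ribosome biogenesis list was higher in hMYC-ER. RNA quality of hlk array 7 is excluded as the cause, with a median of 0.545 without it. The choice among 3 scalings is excluded too, since the list median was 0.407 to 0.535 and its lower quartile at least 0.183 under each of them. MYC activity may explain the shift, but lineage could do so too. These were not separated because 0 of 3 hlk arrays reached the B cell list mean of the lowest hMYC-ER array. The models also do not contrast high with low MYC in a known way. The level of the transgene was not analysed, myca was higher in hlk (-4.29) and mych was higher in hMYC-ER (2.77). With an estimated correlation the list's adjusted p was 0.140.

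The oxidase genes ncf1, cyba and ncf4 were higher in hMYC-ER. The other 9 neutrophil markers had a median of -0.363 (range -1.88 to 1.95). Their upper quartile, 0.0715, lay below the lowest 95% bound of the 3 genes, 0.938. None of the 9 differences reached those of ncf1 (7.93) or cyba (3.94), which argues against neutrophils as the only source of these 2. For ncf4 neutrophils are not excluded, because alox5ap rose by at least 1.95, more than ncf4 (1.59). The markers were also dim (list median levels 5.99 in hMYC-ER and 5.75 in hlk), and without hlk array 7 the list median was 0.311. No biological explanation was tested for this pattern.

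Over the 84 splits of the arrays into 6 and 3, the real grouping gave the most changed probe sets (1 of 84, 2932 against at most 13) and genes (1 of 84, 1932 against at most 6), so a random grouping is excluded for these. For single lists, as small an adjusted p came from 1 split for B cells (smallest other 2.4e-05), 4 for ribosome biogenesis (smallest other 4.2e-12), 6 for MYC-associated metabolism (1.8e-04) and 6 for heat shock (1.9e-05). For B cells no other split came near the 1.1e-11 of the real grouping, which argues against a random grouping. It does not exclude it, since 1 of 84 is the lowest share possible, 13 biology and 12 marker lists were tested, and this test was chosen afterwards. For ribosome biogenesis a random grouping is not excluded, since another split gave a smaller camera adjusted p than the 1.2e-09 of the real grouping. Nor is it excluded for the other 2 lists, or for the number of shifted lists, where 40 splits gave 4 or more and the highest other split gave 9.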

How the results depend on the processing

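The fit on signals as deposited and the closer look at hlk array 7 were chosen only after the result was seen. Of the 85 changed genes among the 101 named, 68 stayed changed in every alternative limma fit run on single genes, which covers scaling, floors, filters, variance models, weights, the mean of probe sets and single arrays left out, and 17 did not. The exact rank test called none of them. The call of 5 of these 17 survived the removal of every single array. No paired analysis was possible because the labels link no hMYC-ER array to an hlk array by pair or litter. The sample numbers, which run from 1 to 9 over the series, carry no pairing. Signals near the floor limit the dim markers, and 9 arrays limit all calls.

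With a 2-fold minimum, 1889 probe sets (845 higher in hlk) and 1154 genes (511 higher in hlk) changed. At an unadjusted p under 0.001 these were 1520 probe sets (823 higher in hMYC-ER, 697 in hlk) and 975 genes (535 and 440). The exact rank test called 0 probe sets and 0 genes in either direction, as its smallest p without ties is 0.0238. Without single arrays, 2427 to 2974 probe sets and 1607 to 1978 genes changed. The distance between minus within models moved to 0.137 without the dimmest probe sets, and the causes of this and of the following changes were not tested.

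An estimated correlation ended the calls of ribosome biogenesis (0.140), MYC-associated metabolism (0.175) and heat shock (0.140). Without the dimmest probe sets, T cell identity (0.0299), chemokine and adhesion (0.00283) and neutrophil genes (0.0323) passed, and a floor of 1 made kidney, gut and pancreas markers pass (0.0359). Ribosomal proteins turned under median centring (0.267). Directional fry, which tests a list by itself, passed T cell identity (1.5e-04), T-ALL oncogenes (0.00171), ribosomal proteins (0.00618), apoptosis and growth arrest (0.0126), chemokine and adhesion (3.9e-06), neutrophil (2.5e-05), stromal (0.0260), neural (9.1e-04) and kidney (0.0177) lists, and turned interferon (0.510). Mixed fry, which ignores direction, passed T cell identity (2.0e-08), V(D)J (2.2e-09), T-ALL oncogenes (2.0e-08), ribosomal proteins (2.6e-06), apoptosis (1.4e-07), chemokine (2.8e-10), interferon (1.8e-09), glycolysis (1.75e-07), oxidative phosphorylation (9.5e-08), neutrophil (1.6e-08), macrophage (1.7e-08), liver (0.0334), neural (1.95e-08) and kidney (0.0425) lists.

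Without single arrays, adjusted p ran from 0.00199 to 0.935 for cell cycle (turned without hlk array 9), 0.333 to 0.960 for oxidative phosphorylation, 0.572 to 0.963 for macrophage, 0.269 to 0.839 for muscle, 0.0364 to 0.419 for liver, 0.0332 to 0.849 for epidermis and 0.0332 to 0.285 for kidney lists. Differences ran from -0.54 to 0.53 for mycn, -0.50 to 2.44 for rag2, -0.43 to 0.053 for ptena and -0.88 to 0.13 for notch1a. Also turned were mycn under median centring (-0.066) and notch1b with a floor of 64 (-0.063). None of these 5 genes passed with all arrays.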

Other observations

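The genes in the first 2 paragraphs of this part were chosen only after the result was seen. The zinc finger gene egr2b stood at 13.99 ± 0.72 (SD, n = 6) against 8.82 ± 1.26 (SD, n = 3), a difference of 5.16 (SE 0.59, adjusted p 5.9e-04), and cd81a, which encodes a tetraspanin partner of the B cell receptor complex in mammals, differed by 5.38 (SE 0.42, adjusted p 7.0e-05, 2 of 3 probe sets). With all 3 hlk arrays at the floor, the haematopoietic factor genes gata2a and hhex were at least 44.4-fold and 9.26-fold higher (adjusted p 3.5e-06 and 1.7e-04). The kinase gene sgk1 (4.98, adjusted p 2.8e-04), the TGF-beta receptor gene tgfbr2b (5.00, adjusted p 4.6e-04) and the migration regulator klf2a (3.99, adjusted p 0.00619) were higher as well.

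In hlk, the integrin gene itgae.2 stood at 11.81 ± 0.38 (SD, n = 3) against 6.66 ± 0.47 (SD, n = 6) in hMYC-ER, a difference of -5.15 (SE 0.30, adjusted p 1.4e-05). The DNA polymerase mu gene polm, whose product joins ends in V(D)J recombination, differed by -4.55 (adjusted p 0.00153), and the cytokine signalling inhibitor socs1a by -3.73 (adjusted p 0.00102, both probe sets). The homeobox gene irx7 (-4.84, adjusted p 9.9e-05) and the transcription factor genes hand2 (-4.67, adjusted p 6.5e-04) and sox11a (-4.43, adjusted p 0.00142, 3 of 3 probe sets) were also higher in hlk.

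In the second B lineage list, id3 (2.82), plcg2 (1.83), ralgps2 (1.93), rasgrp3 (2.96) and swap70b were higher in hMYC-ER, and bcl6ab (-0.48) and ets2 (-0.06) did not pass. In the second T lineage list, dusp5 (3.90) was higher in hMYC-ER, and arl4cb (-0.16), dusp4 (0.43), plcg1 (-0.45) and rorcb (0.44) did not pass.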
